A study of Homo sapiens with 11 samples.

How the data were processed

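Chromatin from KYSE70, TT, HCC95 and H9 cells was crosslinked with formaldehyde and sheared by sonication, per the labels' protocols. SOX2 was precipitated from all 4 lines and p63 from the 3 squamous lines. The labels give the same culture medium for every line, H9 included. Of the 11 libraries, the 4 inputs were not analysed here, and the 7 precipitated libraries each came with 1 list of summits. Reads were aligned with Bowtie to hg18 and peaks called with MACS 1.4.1, per the submitters' processing notes. The thresholds, the use of the inputs and the read depth are not given in the sources used here. The lists were made per library and not pooled.

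Each deposited list gives windows of 601 bp without a header, and the middle of the window was taken as the summit. That the windows were widened from summits is inferred from their equal size. The signal in the deposited lists is a whole-number height per summit that the authors' peak caller gave. It was used only to describe, rank or filter summits within a list, since no scaling between libraries is recorded. All coordinates are hg18, counted from 1. The gene annotation at hand was of another build, so no coordinate was matched to a gene, and the planned tests of gene lists and sequence motifs were not run.

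A summit counted as shared when a summit of the partner list lay within 250 bp, each summit counting once. Shares have exact Clopper-Pearson 95% intervals. These intervals cover counting error only, and neighbouring summits are not independent. The background was the same share after the whole partner list was moved by 1 random distance of 20 to 500 kb in either direction, 1000 times with a fixed seed. Regions were made by joining summits of the lists compared that lay within 250 bp of each other. A Jaccard index was the number of regions in both lists over the number in either. The share computation was tested on the SOX2 list of each line (5371 to 12504 summits) and a simulated p63 list of that line's p63 list length. Planted p63 summits were placed inside the 250 bp limit, so the test checks the counting and not realistic summit spacing. Planted shares of 0, 5 and 20% were recovered as 0.0943 to 0.408%, 5.15 to 5.28% and 20.0 to 20.1%. No 2 lists were alike enough to be 1 library, since the highest share between any 2 was 61.1%.

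The squamous lines were the replicates of each factor, and SOX2 and p63 lists of 1 line were paired because they came from the same line. The p-values therefore rest on 3 lines, with 1 library per antibody and line. The sign flips act on the differences per line or pair of lines. The other tests rank the actual labelling of the lists or shares among its possible rearrangements and do not measure the spread between lines. Comparisons used exact permutation tests. The 6 pairings of p63 lists with SOX2 lists, 4 distinct swaps of the factor labels within lines, the 4 choices of the list called H9 and 8 sign flips allow p-values no smaller than 0.167, 0.25, 0.25 and 0.25. The unpaired permutation of 6 shares allows no less than 0.1. None of these exact tests could reach 0.05. With the pairing by line as the block, the SOX2 share minus the p63 share was the same -3.41 percentage points (exact sign-flip p = 0.5).

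The groups, tests, distances, alternatives and rule for named regions were fixed before the data were examined. Regions were ranked by the mean over the lists present of the summit's height percentile within its list. The text names the first 6 with SOX2 and p63 in all 3 squamous lines and no H9, and the first 4 of each other class: SOX2 only in the 3 squamous lines, p63 only, SOX2 in all 4 lines without p63, all 7 lists, and H9 only. The rule also takes the highest summit of each list and the densest clusters, joined at 12500 bp, of regions with both factors in all 3 squamous lines. Alternatives were distances of 100, 500 and 1000 bp, the upper part of each list by height, lists of equal length, leaving out chromosome 3, leaving out regions in all 7 lists, leaving out each line, moves of 1 to 5 Mb, the mean in place of the median height, and pairs at up to 500 bp. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.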

Results

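The data comprised chromatin immunoprecipitation sequencing (ChIP-seq) of SOX2 and p63 in 3 squamous carcinoma cell lines with amplified SOX2, and of SOX2 in H9 human embryonic stem cells. SOX2 is an HMG-box transcription factor of pluripotent cells and of the foregut lineage, and p63 is a p53-family transcription factor of basal squamous epithelium. KYSE70 and TT are esophageal squamous carcinoma lines and HCC95 is a lung squamous carcinoma line. Each antibody gave 1 list of summits per line, so that the 3 squamous lines served as the replicates of each factor (n = 3) and H9 had no replicate. The 7 lists held 53238 summits. SOX2 lists held 8484 summits in KYSE70, 12504 in TT, 5371 in HCC95 and 5712 in H9. The p63 lists held 4837 summits in KYSE70, 9801 in TT and 6529 in HCC95. The median summit height was 14, 13, 13 and 9 for SOX2 in KYSE70, TT, HCC95 and H9, and 14, 13 and 18 for p63 in KYSE70, TT and HCC95. The number of reads behind each list is unknown, so list lengths and heights were not read as differences in binding between libraries.

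The first comparison asked how often SOX2 and p63 occupied the same sites within a squamous line. A p63 summit lay within 250 bp of 11.4% of the SOX2 summits in KYSE70 (964 of 8484, 95% interval 10.7 to 12.1), 17.4% in TT (2175 of 12504, 16.7 to 18.1) and 17.7% in HCC95 (950 of 5371, 16.7 to 18.7). The mean was 15.5% ± 3.57 (SD, n = 3). Moving the whole p63 list by a random distance of 20 to 500 kb left a mean of 0.211% ± 0.103 (SD, n = 3). The highest of 3000 moved lists reached 0.616%. The share in place was 80.2-fold ± 25.9 (SD, n = 3) above the moved lists. Moved summits need not land at accessible sites, so this background, used for each fold given here, does not account for accessibility. Counted from p63, 19.9% of p63 summits in KYSE70, 22.2% in TT and 14.6% in HCC95 had a SOX2 summit (mean 18.9% ± 3.93, SD, n = 3). The SOX2 share minus the p63 share was -3.41 percentage points ± 5.98 (SD, n = 3; two-sided exact permutation p = 0.4, where the smallest possible is 0.1), within the spread between lines. Both shares count nearly the same pairs, so their difference is set by the list lengths and does not compare the factors. Most close pairs were very close. Of the SOX2 summits with p63 within 1000 bp, 80.6% in KYSE70, 82.6% in TT and 87.8% in HCC95 had it within 250 bp.

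**Figure D1:**
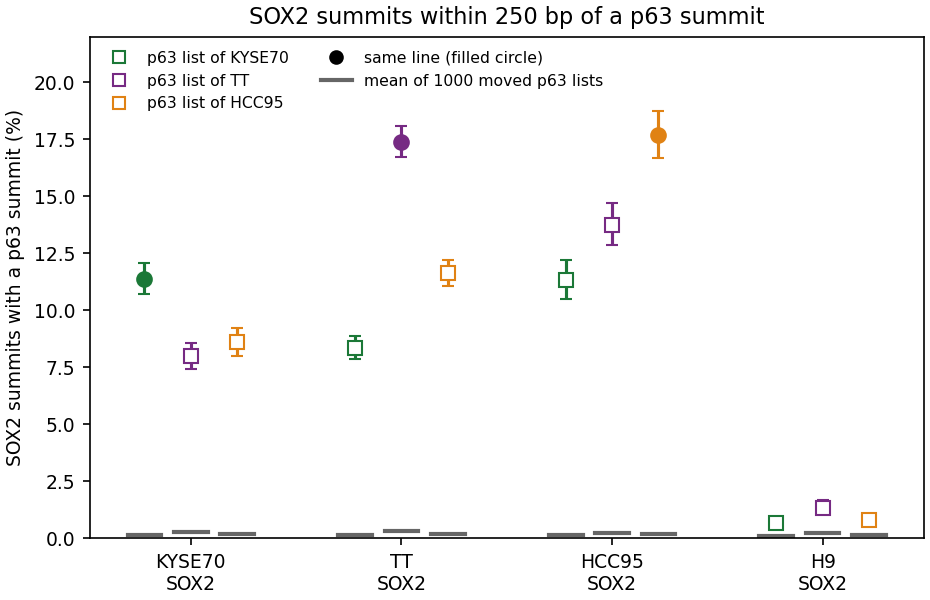
Percent of the SOX2 summits of each line (horizontal axis) with a p63 summit within 250 bp, for the p63 list of each squamous line (colours). Filled circles are same-line pairs, open squares other-line pairs, bars exact binomial 95% intervals, and grey lines the mean of 1000 moved p63 lists. Same-line shares lie between 11.4 and 17.7%, and the H9 shares at or below 1.33%.

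Sites with both factors included regions bound in every squamous line and absent from the H9 list. The highest-ranked such region lay on chromosome 5 at 137868627 to 137868695 (hg18; first and last summit), where SOX2 heights were 80, 110 and 68 and p63 heights 82, 52 and 36 in KYSE70, TT and HCC95. The next were on chromosome 1 at 201986998 to 201987064 (SOX2 50, 41 and 30, p63 88, 49 and 47), chromosome 9 at 133498771 to 133498857 (SOX2 47, 29 and 35, p63 91, 36 and 56), and chromosome 14 at 69249772 to 69249844 (SOX2 26, 44 and 25, p63 86, 62 and 68). Chromosome 2 held the other two, at 55920314 to 55920363 and at 177743292 to 177743409, and the second of these contained the highest p63 summit of HCC95, with a height of 131. Genes at these regions were not analysed here.

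At sites with both factors the summits were offset more than summits of 1 factor were between lines. Within a line the median distance from a SOX2 summit to its p63 partner was 63 bp in KYSE70, 55 bp in TT and 58 bp in HCC95 (mean 58.7 bp ± 4.04, SD, n = 3), and 44.1% ± 2.75 of pairs lay within 50 bp. Between lines the median distance was 42.0 bp ± 1.73 (SD, 3 pairs of lists) for SOX2 and 18.3 bp ± 1.53 for p63, with 57.1% ± 2.12 and 84.5% ± 1.56 of pairs within 50 bp. These distances were described and not tested.

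**Figure D2:**
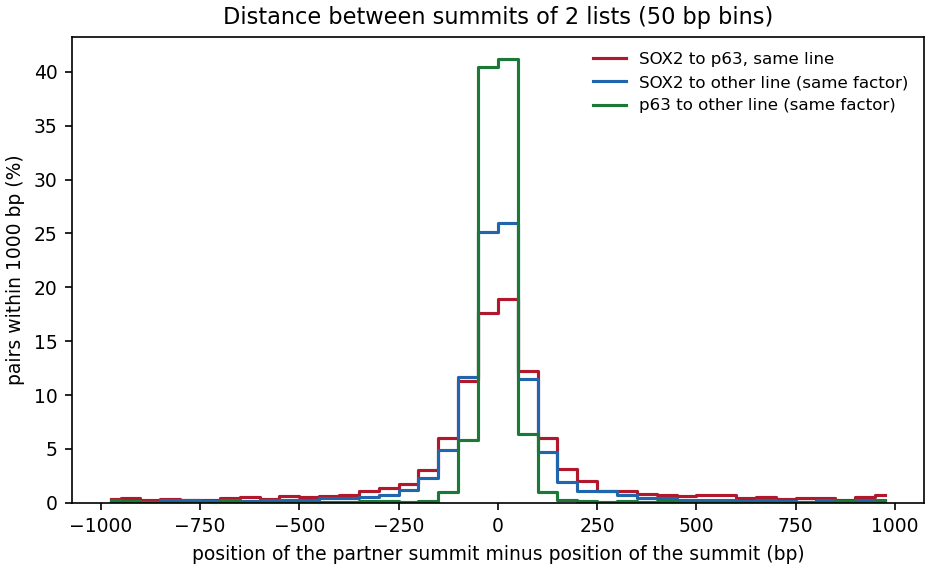
Position of the nearest partner summit minus that of the summit (bp, bins of 50 bp) as a percent of pairs within 1000 bp, for SOX2 to p63 in the same line, SOX2 to SOX2 in another line and p63 to p63 in another line. The p63 pairs are the most concentrated around 0, with 84.5% of pairs at or below 250 bp lying within 50 bp.

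Shared summits were taller than unshared summits in all 3 lines for both factors. For p63, the median height at summits with and without SOX2 was 21 and 13 in KYSE70, 16 and 12 in TT, and 20 and 17 in HCC95, a mean ratio of 1.38 ± 0.222 (SD, n = 3). For SOX2 the medians were 17 and 14, 14 and 13, and 14 and 13, a mean ratio of 1.12 ± 0.0793 (SD, n = 3). The share of SOX2 summits with p63 was lowest in the lowest of 4 classes of SOX2 height and highest in the top class, at 7.25 and 17.7% in KYSE70, 12.3 and 21.8% in TT, and 12.2 and 22.8% in HCC95.

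The next comparison asked whether co-location followed the cell line. SOX2 summits met the p63 list of their own line more often than the p63 list of another line in each of the 3 lines. The other-line shares averaged 10.3% ± 2.32 (SD, 6 pairs of lists) and ranged from 7.98 to 13.8%. The same-line mean was 5.21 percentage points higher, the largest difference among the 6 pairings of lists (one-sided exact permutation p = 0.167, the smallest that this permutation of lists allows). Counted from p63, which was done after the values were seen, the own-line share was the highest in TT only. KYSE70 p63 summits met the TT SOX2 list at 21.6% and their own at 19.9%, and HCC95 p63 summits met the TT list at 22.3% and their own at 14.6%. The TT SOX2 list was the longest. The same-line mean counted from p63 was 5.22 percentage points above the other-line mean of 13.7% ± 6.74 (SD, 6 pairs of lists; one-sided exact permutation p = 0.167). With lists of equal length the own-line share of p63 summits was the highest in each line, at 13.8% in KYSE70, 14.6% in TT and 15.1% in HCC95, against 6.18 to 12.8% with other lines.

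Each list resembled the same factor in another line more than the other factor in its own line. Between lines the Jaccard index, the number of regions in both lists over the number in either, averaged 0.156 ± 0.0133 (SD, 3 pairs of lists) for SOX2 and 0.257 ± 0.0653 for p63, against 0.0909 ± 0.0155 for SOX2 and p63 of 1 line. The same-factor mean was 0.115 higher (one-sided exact permutation p = 0.25, the smallest possible). The p63 lists were more alike than the SOX2 lists in each pair of lines, by 0.101 ± 0.0785 (SD, 3 pairs of lines that share lists; two-sided exact sign-flip p = 0.25, the smallest possible). This last difference was looked for after the values were seen, and it was 0.0227 for KYSE70 and TT, the pair without HCC95. The closest pair was HCC95 and TT for p63, where 61.1% of HCC95 p63 summits had a TT p63 summit. For SOX2 the highest share was 41.7%, for HCC95 summits in the TT list.

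**Figure D3:**
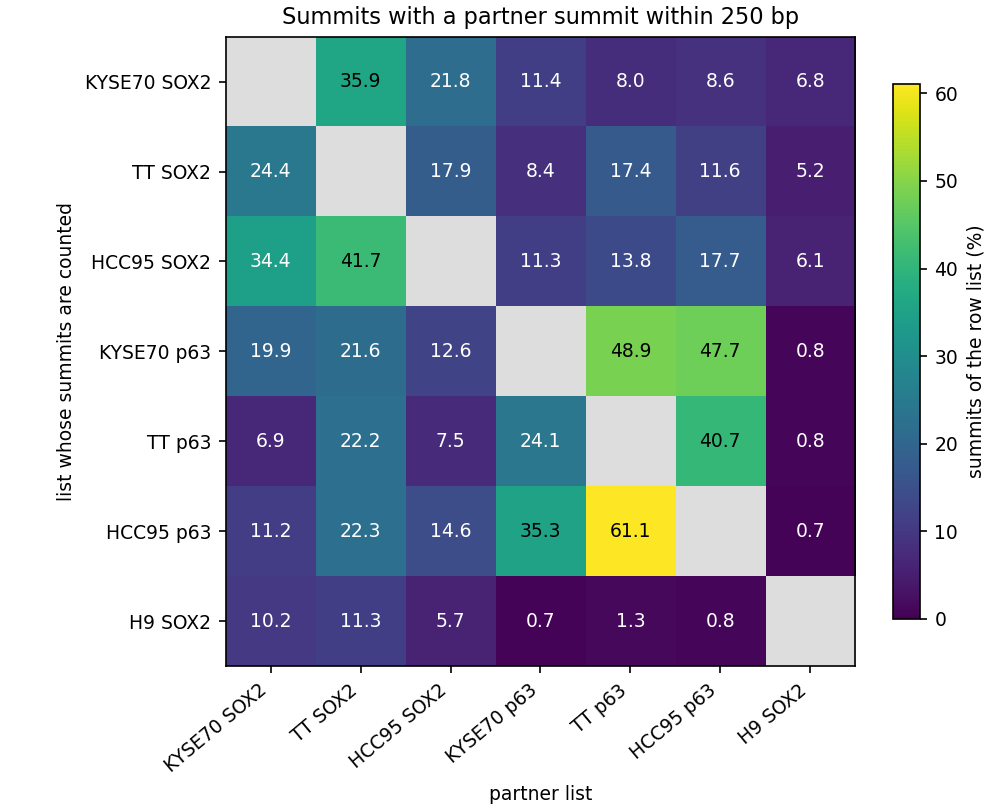
Percent of the summits of each list (rows) with a summit of the partner list (columns) within 250 bp. Colour runs from 0 to 61.1%. The highest share is that of HCC95 p63 summits in the TT p63 list, and the H9 SOX2 list shares 5.74 to 11.3% of its summits with squamous SOX2 lists and 0.683 to 1.33% with p63 lists.

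The comparison with embryonic stem cells asked how far SOX2 sites differ between the cell types. Squamous SOX2 summits recurred far more in another squamous line than in the unreplicated H9 list. The read depth of that list is unknown, and SOX2 sites missed in it would also lower the share with H9. On average 29.3% ± 8.46 (SD, n = 3) of the SOX2 summits of a squamous line were shared with any given other squamous line, against 6.03% ± 0.841 with H9, a difference of 23.3 percentage points ± 8.06 (SD, n = 3). The difference was largest when H9 was the list set apart from the other 3 SOX2 lists (one-sided exact permutation p = 0.25, the smallest possible). The H9 overlap was still 47.2-fold ± 9.09 (SD, n = 3) above moved lists. Squamous SOX2 summits shared with H9 were taller than the others, with median heights of 20 and 14 in KYSE70, 18 and 13 in TT, and 16 and 13 in HCC95. H9 summits shared with a squamous SOX2 list were not taller, with a median of 9 at the 891 shared summits and 9 at the 4821 others. H9 summits met p63 rarely, 0.934% ± 0.348 (SD over the 3 p63 lists), which was 5.56-fold ± 0.506 above moved lists.

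p63 was found less often at the SOX2 sites that squamous cells shared with H9 than at the others. Among SOX2 summits shared with H9, p63 of the same line was present at 4.66% in KYSE70 (27 of 580, 95% interval 3.09 to 6.70), 7.44% in TT (48 of 645, 5.54 to 9.75) and 8.54% in HCC95 (28 of 328, 5.75 to 12.1). Among SOX2 summits without H9 it was present at 11.9% in KYSE70 (937 of 7904, 11.2 to 12.6), 17.9% in TT (2127 of 11859, 17.2 to 18.6) and 18.3% in HCC95 (922 of 5043, 17.2 to 19.4). The share with H9 minus the share without averaged -9.15 percentage points ± 1.73 (SD, n = 3). It was negative in 3 of 3 lines (two-sided exact sign-flip p = 0.25, the smallest possible with 3 lines). The share without H9 was 2.37 ± 0.206 (SD, n = 3) times the share with H9.

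**Figure D4:**
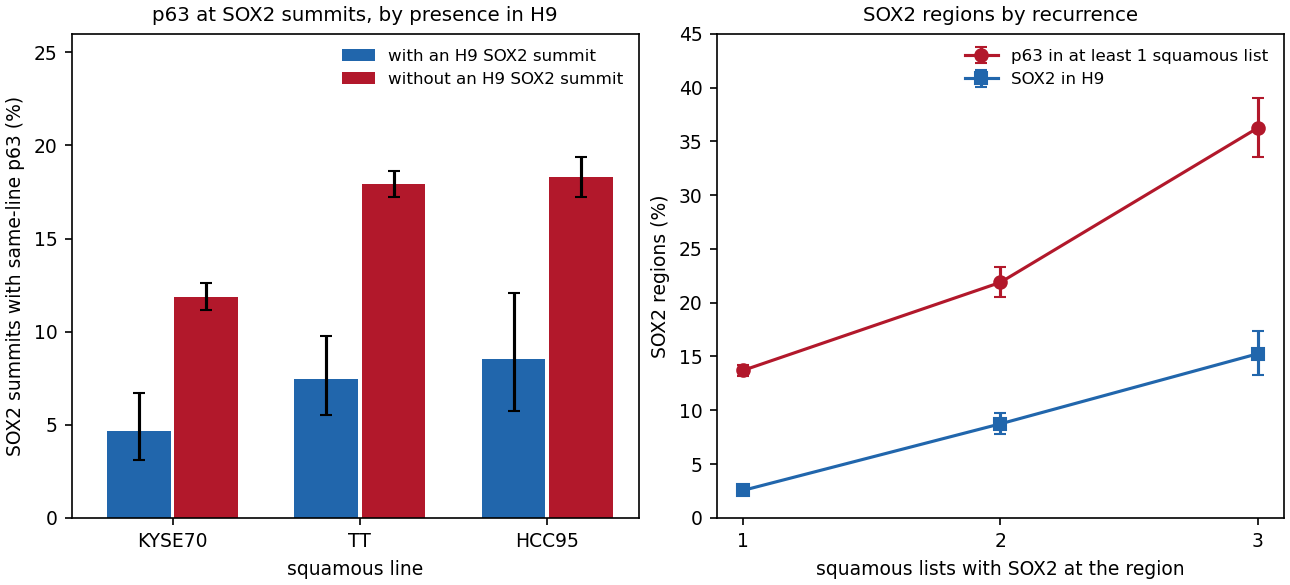
Left, percent of SOX2 summits with a same-line p63 summit in each squamous line, for summits with (blue) and without (red) an H9 SOX2 summit within 250 bp. Right, percent of SOX2 regions with p63 in at least 1 squamous list (red) and with SOX2 in H9 (blue), by the number of squamous SOX2 lists. Bars are exact binomial 95% intervals. The red bars exceed the blue in every line, and the red line rises from 13.7 to 36.3%.

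Joining summits of all lists within 250 bp gave 36123 regions, of which 25726 were in 1 list only. SOX2 was present in all 3 squamous lines at 1219 regions and p63 at 1842, and both factors in all 3 lines at 220. With each list moved independently these counts averaged 0.081, 0.072 and 0 over 1000 moves. Of the 220 regions, 212 lacked an H9 summit. SOX2 in all 3 lines without any p63 list was found at 777 regions, and p63 in all 3 lines without any squamous SOX2 list at 971. SOX2 in all 3 squamous lines and H9 was found at 186 regions, 157 of them without p63, and 8 regions were in all 7 lists. The H9 list had 4792 regions of its own. The 220 regions were scattered: joined at the cluster distance given with the processing, they formed 219 clusters, of which 1, on chromosome 1 at 207651730 to 207656252, held 2 regions.

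Co-location rose with recurrence, counted with the other factor in any squamous list and without matching summit height. With same-line p63 the share was higher at recurring than at other SOX2 summits in each line, but only 19.1 against 16.6% in TT. p63 was present in at least 1 squamous list at 13.7% of the 15584 regions with SOX2 in 1 squamous line (95% interval 13.2 to 14.2), 21.9% of the 3559 regions with SOX2 in 2 lines (20.5 to 23.3) and 36.3% of the 1219 regions with SOX2 in 3 lines (33.6 to 39.0). The corresponding shares with an H9 summit were 2.55%, 8.74% and 15.3%. From the side of p63, SOX2 was present in at least 1 squamous list at 15.6% of the 9328 regions with p63 in 1 line, 32.6% of the 3155 in 2 lines and 47.3% of the 1842 in 3 lines, and the share with an H9 summit rose from 0.547% (95% interval 0.407 to 0.718) through 0.983% to 1.19% (0.750 to 1.80).

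Regions with 1 factor had some of the tallest summits. SOX2 without p63 and without H9 peaked on chromosome 12 at 31793633 to 31793701 with heights of 100, 90 and 63 in KYSE70, TT and HCC95, chromosome 11 at 12821252 to 12821262 (72, 86 and 64), chromosome 13 at 94604454 to 94604470 (108, 56 and 60) and chromosome 17 at 36813958 to 36813976 (55, 62 and 44). p63 without SOX2 peaked on chromosome 9 at 118489334 to 118489343 (158, 101 and 91), chromosome 12 at 55776337 to 55776361 (114, 78 and 93), chromosome 7 at 74995394 to 74995407 (98, 66 and 86) and chromosome 2 at 113166794 to 113166810 (137, 57 and 87). SOX2 in all 4 SOX2 lists without p63 was led by the unplaced sequence of chromosome 17 at 85273 to 85359, with heights of 219, 174 and 103 in KYSE70, TT and HCC95 and 45 in H9. Chromosome 9 at 139316575 to 139316590 (149, 226, 65 and 34), chromosome 20 at 59445304 to 59445377 (90, 121, 66 and 26) and chromosome 1 at 93317286 to 93317309 (62, 57, 52 and 34) followed. Regions in all 7 lists included chromosome 1 at 180337264 to 180337400, chromosome 18 at 50027573 to 50027728, chromosome 20 at 51917657 to 51917887 and chromosome 12 at 120923793 to 120924083. The tallest H9-only summits lay on chromosome 20 at 26138120 and 26137052 (87 and 65), chromosome 6 at 119600306 (77) and chromosome 17 at 66540677 (62). Repeats at these positions were not analysed here.

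The highest summit of the KYSE70, TT and H9 SOX2 lists was 1 site on chromosome 1 at 91625556 to 91625562, with heights of 312, 384 and 111. No HCC95 SOX2 summit and no p63 summit fell in that region. Whether this site, the unplaced chromosome 17 site or the highest p63 sites are repeats was not analysed here. Reads from several repeat copies placed at 1 position would raise the heights given for them. The highest SOX2 summit of HCC95, 103, was the unplaced chromosome 17 site. The highest p63 summit of KYSE70, 186, lay on chromosome 11 at 64945367, where SOX2 heights were 11 in KYSE70 and TT, and that of TT, 142, lay on chromosome 1 at 142722205 without SOX2.

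The last comparison asked whether the chromosome that carries SOX2, chromosome 3, held more SOX2 summits in the amplified lines. Over the whole chromosome it did not stand apart, though such a share could miss a difference in a smaller stretch. Chromosome 3 held 6.81% of SOX2 summits in KYSE70, 5.62% in TT and 7.17% in HCC95, against 6.37% in H9, a mean difference of 0.162 percentage points with an SD between lines of 0.810 (n = 3; one-sided exact permutation p = 0.5, where the smallest possible is 0.25). The sign turned with HCC95 left out, at -0.155, and with lists of equal length, at -0.496. It held 6.31, 5.10 and 6.17% of p63 summits in KYSE70, TT and HCC95. From 170 Mb to its end, a start chosen after the values were seen, chromosome 3 held 1.74% ± 0.319 (SD, n = 3) of squamous SOX2 summits and 1.33% of H9 summits (one-sided exact permutation p = 0.25, the smallest possible). By line the SOX2 share there was 1.51% in KYSE70, 1.61% in TT and 2.10% in HCC95. The p63 lists held 1.46% ± 0.141 (SD, n = 3) there, with 1.30% in TT, below H9.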

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

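Leaving out unplaced sequences, leaving out SOX2 summits near an H9 summit, and the omission of each line for heights, distances and chromosome 3 were chosen after the data were seen, as were the similarity of p63 against SOX2 lists, same-line sharing counted from p63, the height classes and the recurring summits. In 210 alternatives to 30 results, 164 kept their direction or stayed within the spread or 1.5 times the count, 43 moved further and 3 turned or lost their direction. The comparisons of same-line with other-line sharing, same-factor with same-line similarity, squamous lines with H9, and p63 at sites with and without H9 kept their direction under each alternative run on them. Leaving out regions in all 7 lists removes sites with both H9 and p63, so it lowers the last difference by construction, to -10.6 percentage points. With no exact test able to pass 0.05, no call could be gained or lost. At 100 bp the mean share of SOX2 summits with p63 was 11.3%, that of p63 summits with SOX2 13.7%, and 4 regions were in all 7 lists, against 16 at 1000 bp. A narrower or wider distance has these effects by construction. Pairs at up to 500 bp had a median distance of 66.7 bp.

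Keeping the upper part of each list by height left, by construction, 4242, 6252 and 2685 SOX2 summits in KYSE70, TT and HCC95, 2418, 4900 and 3264 p63 summits, and 2856 in H9. Regions in all 3 squamous lists then numbered 650 for SOX2, 1083 for p63, 92 for both, 452 for SOX2 without p63 and 95 for SOX2 with H9. None (0) were in all 7 lists, and the median distance was 53.3 bp, for which the cause was not tested. Lists of equal length held 4837 summits each. They gave a p63 share of 14.5%, a SOX2 minus p63 share of 0 by construction, 779 regions for SOX2 in all 3 lines, 115 for both factors, 517 for SOX2 without p63, 2 in all 7 lists, and a chromosome 3 difference of -0.496 percentage points, turned in sign, for which the cause was not tested.

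Without 1 line in turn, 2 lists suffice for a region, so counts rise by construction: 1854 to 3066 for SOX2, 2312 to 3992 for p63, 345 to 461 for both, 1303 to 2395 for SOX2 without p63, 1359 to 2607 for p63 without SOX2, and 215 to 407 for SOX2 with H9. The chromosome 3 difference ranged from -0.155 (without HCC95) to 0.618 percentage points. The SOX2 minus p63 share kept its sign but ranged from -6.69 to -0.835, and with the pairing by line as the block it was -3.41 (exact sign-flip p = 0.5). Moves of 1 to 5 Mb lowered the mean count of chance regions with SOX2 in all 3 lines from 0.081 to 0.046. The planned tests of motifs and gene lists were not run. Read depth is unknown, so whether a site missing from a list was unbound or below detection cannot be said.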

Other observations

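The tests against sites that any immunoprecipitation recovers, against regional density at sites with both factors, against SOX2 height and recurrence at H9-shared sites and against unequal list lengths were chosen only after the results were seen, as were the regions and chromosomes named here outside the fixed rule.

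Regions listed for each factor in 1 line only mostly had both factors in the same line. Read depth is unknown, so such a site may be unbound or below detection in the other lines. Of 1066 regions with SOX2 in exactly 1 squamous line and p63 in exactly 1, 911 had both in the same line (85.5%, exact binomial 95% interval 83.2 to 87.5). These were 128 regions in KYSE70, where the totals would give 25.7, 632 in TT, where they would give 456, and 151 in HCC95, where they would give 38.3. Chromosome 19 held 2.05% of SOX2 and 2.96% of p63 summits in HCC95, against 4.15 and 3.78% in KYSE70, 4.998 and 4.32% in TT, and 3.52% of SOX2 summits in H9. Chromosome 13 held 3.69% of SOX2 and 2.67% of p63 summits in HCC95, against 2.38 and 1.76% in KYSE70, 2.50 and 2.06% in TT, and 2.78% of SOX2 summits in H9.

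SOX2 and p63 coincided at 7.98 to 17.7% of SOX2 summits over the 9 squamous pairs of lists. Sites that any immunoprecipitation recovers in any cell would make H9 SOX2 summits meet the squamous p63 lists too. At most 1.33% of H9 SOX2 summits did (upper 95% bound 1.66%). p63 was not precipitated from H9, so sites recovered without specific binding only in squamous chromatin, or missed in the H9 list, are not covered. Regional density of summits, from copy number or gene-rich domains, would survive moving the lists, but the highest share after moving was 0.616%. Copy number that raised both libraries of a line at the same position would be lost on moving, as joint binding would. The inputs were not analysed, so that route is not covered. Accessible sites of squamous cells that both antibodies recover cannot be told apart from joint binding: heights of SOX2 and p63 at shared summits were only weakly related across sites, which are not independent replicates (mean rank correlation 0.0982 ± 0.0504, SD, n = 3), against 0.428 ± 0.0404 for 1 factor between lines, but the value was not at or below 0, and no accessibility data were used here. Joint binding of the factors in squamous cells was not tested and stays open.

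p63 was rarer at SOX2 summits that H9 shares. SOX2 height works against this pattern, since H9-shared summits were taller (mean ratio of medians 1.35 ± 0.104, SD, n = 3) and the share with p63 was higher in the top than in the lowest height class of each line. Recurrence works against it too, since H9-shared summits recurred in another squamous line more often than the others (by 34.1 percentage points ± 5.27, SD, n = 3), and p63 was more frequent at recurring than at other SOX2 summits, at 17.5 and 6.57% in KYSE70, 19.1 and 16.6% in TT, and 23.5 and 10.8% in HCC95. Within 4 classes of SOX2 height the difference was -11.6 percentage points ± 1.30 (SD, n = 3) and among recurring summits -14.4 ± 2.33. These alternatives were added after the data were seen and first taken as the tests. The relations above would themselves widen the difference, so its persistence was foreseeable and is weak evidence against either explanation. Among H9-shared summits alone the p63 share was lowest in the lowest height class of each line but did not rise steadily. From class 2 to class 4 it fell from 6.25 to 4.33% in KYSE70 and from 11.1 to 8.00% in HCC95, and rose from 5.33 to 8.16% in TT. The difference between squamous and embryonic stem cells that the design names, sites that the SOX2 antibody recovers in any cell type, and repeats were not tested as reasons and stay open.

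The pairing of sites listed in 1 line only was weighed in the same way. Unequal list lengths would give 48.8% of such regions in 1 line, below the 85.5% seen. Regional density that differs between lines, as copy number would make it, would keep the percentage high among chance meetings of moved lists, but there it was 49.2% (upper 95% bound 49.7%), against 45.2% from their totals. These meetings were pooled over moves of the same lists and count the same summits repeatedly, so that bound is too narrow. The small excess over the totals was not tested, and a part from regional density stays open. Moved lists cannot show whether copy number let both factors pass the threshold at the same site in 1 line only. The inputs were not analysed, so that stays open too. Accessibility that differs between lines was not tested and could give the same pattern as joint binding.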
